A study of Homo sapiens with 29 samples.

How the data were processed

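RNA was measured in 29 samples of HEK293 cells, of which 21 are RIP libraries and 8 siRNA libraries, grouped by the compartment, antibody or siRNA that the labels give. Per the labels' protocols, lysates were incubated with beads carrying hnRNPA1 antibody or normal IgG, the bound RNA was released with proteinase K, and stranded total RNA libraries were made without further fragmentation. RNA of the siRNA samples was extracted with Trizol and made into libraries with the same kit. The protocol text describes the RIP RNA as degraded and states that 1 sample gave a poor library without naming it.

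The authors deposited gene values of the 8 siRNA libraries as a signal that is never negative. From the values, it was taken as read counts per gene scaled by 1 factor per library. Per the submitters' processing notes, Partek, STAR 2.7.8a, DESeq2 and the build hg38 were used, with no role or order given. How reads were assigned to genes is not given in the sources used here. In each library 82.2% to 84.7% of the values were whole multiples of 1 step within a tolerance of 0.02, and the rest were not, so the values were not treated as counts. The step gave the estimated reads per library. The table holds 16382 genes by Ensembl ID, of which 16358 matched a symbol and 24 did not. With its header and treatment line it has 16384 lines, which equals the column limit of a spreadsheet, and its IDs are sorted, so genes with later IDs may have been cut off.

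The authors deposited 1 peak list per compartment, with a signal score and a p-value and q-value for each 500-base window. With 1 list per compartment no replicates can be compared. The peak caller's version, the genome build and the library used as background are not given in the sources used here. All q-values lie under 0.05. Gene IDs in peak names were matched to symbols, with 38, 10 and 14 genes of the whole-cell, cytosolic and mitochondrial lists unmatched. Of the 14418 peaks with a symbol in the RefSeq table (GRCh38.p14), 95.5% lay within 500 bases of that gene's span, but no RefSeq coordinate was used in place of a listed one.

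Because the design assumed counts or normalised values and the table holds normalised values, the test planned for normalised values was used: limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean (limma-trend), on log2(value + 1), without a replicate block, and Benjamini-Hochberg adjustment over the genes tested. Genes with a value of at least 10 in at least 4 libraries were tested, which leaves 15267. This minimum was set after the file was seen. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Gene lists (22, of which 21 had at least 2 tested members) were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Tests of a single value over the 4 and 4 libraries are exact permutation tests, two-sided. Peaks were compared by Fisher's exact tests, two-sided, among the tested genes, and by window overlap on the same strand with bedtools 2.31.1. Expectations matched on expression come from 10000 random sets drawn within 10 bins of mean expression. A version matched also on the gene's span used bins of both for the 94.0% of tested genes with a span in RefSeq, none of them mitochondrial. Bound genes were tested in the knockdown with cameraPR on the knockdown statistic. Figures were drawn with matplotlib 3.10.9.

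The gene test was tested on simulated data over 15267 genes. Each gene had its mean over the 8 libraries and a spread within groups that was smoothed on the mean. The test recovered 76 of 100 genes changed 1.5-fold and 90 of 100 changed 2-fold, with 6 false calls among 172. The list test found a planted list and called 0 of 20 random lists, and the matched overlap and median tests each called 1 of 20 null cases and found the planted case. In these simulations genes varied independently, genes of like mean had the same spread, and libraries had no structure beyond the siRNA group. The runs thus do not show how the tests behave with the correlation between genes and libraries in these data. Nor do they show the share recovered where genes of like mean differ in spread.

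The text names HNRNPA1, the 10 largest rises and 10 largest falls among genes called at an adjusted p under 0.05 with a symbol and a mean above the median expression, members of each list with the smallest adjusted p, the genes with the 10 highest signal values of each peak list, genes with a peak on the mitochondrial chromosome, and genes bound in all 3 compartments that changed. Lists, design, rule and most alternatives were fixed before the data were examined. Alternatives were a pseudocount of 0.1, no filter, genes above the median expression, the replicate block, each library left out, a fold of at least 1.5, an adjusted p under 0.01, an estimated correlation, the fold change as ranking statistic, the peaks ranked above the median signal value of each list, a q of at most 0.005, a reciprocal overlap of 50% and a preset correlation of 0.05. Quantile normalization, median centring, voom weights and the matched expectations of overlaps, lists and changed genes were added after the data were seen, as were the left-out libraries and scalings of the list tests and of the bound genes, the exact sign-flip tests (two-sided) within same-numbered pairs, and the splits that part every pair. Alternatives meant for counts were not run. Values of single RIP libraries were not analysed here.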

Results

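HEK293 is a human embryonic kidney cell line, and hnRNPA1 is a nuclear RNA-binding protein that takes part in splicing and shuttles to the cytoplasm. The series holds 29 samples of these cells. In 21 of them RNA was recovered with an antibody against hnRNPA1, or with normal IgG as the background, from whole-cell lysate, cytosol or mitochondria (RNA immunoprecipitation, RIP). The whole-cell arm has 3 IgG and 3 hnRNPA1 libraries, the cytosol 4 and 4, and the mitochondria 3 and 4. In the other 8 samples the total RNA of cells given control siRNA (n = 4) or siRNA against hnRNPA1 (n = 4) was sequenced. For the RIP arm, 1 list of peaks per compartment was analysed, with no value per library, so the depth of the RIP libraries is unknown and nothing can be said of their replicate spread. For the siRNA arm, a table of normalised read counts per gene and library was analysed, from which 16614300 (knockdown library 4) to 22063700 (knockdown library 3) reads per library were estimated. Nothing in the labels says that samples of 1 group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

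The first comparison asked which RNAs differ between cells given siRNA against hnRNPA1 and control siRNA. The labels name no other siRNA against hnRNPA1 and no rescue. Effects of losing hnRNPA1 thus cannot be told apart from off-target effects of the siRNA. HNRNPA1 (ENSG00000135486.19), the targeted gene, stood at 18640, 20400, 18610 and 19350 normalised reads in control libraries 1 to 4 and at 6506, 6413, 7185 and 5306 in knockdown libraries 1 to 4. Its mean fell from 19250 ± 841 to 6352 ± 778 (SD, n = 4 each), which left 33.0% of the control level (log2 fold change -1.61, SE 0.09, limma adjusted p = 2.2e-06). Of 15267 genes tested, 252 changed at an adjusted p under 0.05, 103 of them higher and 149 lower in the knockdown, in a fit that does not pair libraries by replicate number. Whether the numbers pair them is open; with the replicate number as a block 1191 genes passed, 605 of them higher and 586 lower. Most of the 252 changes were small, with a median size of 1.39-fold. Only 12 of the 252 genes changed by more than 2-fold, HNRNPA1 among them. With any 1 library left out, the count ranged from 61 (without control library 4) to 254 (without knockdown library 1). It was 73 without control library 1, 138 without control library 2, 156 without control library 3, 74 without knockdown library 2 and 69 without knockdown library 3.

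Among genes above the median expression the largest rise was that of HNRNPH3, another hnRNP protein gene, from 1441 ± 203 to 2766 ± 366 normalised reads (SD, n = 4; log2 fold change 0.94, SE 0.11, limma adjusted p = 0.0014). ATIC, an enzyme of purine synthesis, rose by 0.80 on the log2 scale and EIF3CL, a near-identical copy of the translation initiation factor gene EIF3C, by 0.74. EIF3C itself rose by 0.47, and reads of the pair may be split between them. PHGDH, which catalyses the first step of serine synthesis, rose from 2448 ± 198 to 3987 ± 856, and AARS1, the cytosolic alanyl-tRNA synthetase, from 2242 ± 214 to 3436 ± 535. The rest of the 10 largest rises were CUL7, a cullin of ubiquitin ligases, at 0.75, RPS16, a ribosomal protein gene with processed copies in the genome, at 0.66, IQCB1 at 0.63, TIMELESS, which acts at replication forks, at 0.58, and MYH9, a non-muscle myosin heavy chain, at 0.57.

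Among genes above the median expression, the largest falls after HNRNPA1 were those of ESD, an esterase, from 1484 ± 162 to 778 ± 87.5 normalised reads (log2 fold change -0.93, limma adjusted p = 7.3e-04), and RSRP1 (-0.88). NNT, the proton-pumping transhydrogenase of the inner mitochondrial membrane, fell from 1873 ± 96.0 to 1041 ± 65.1 (log2 fold change -0.85, SE 0.07, limma adjusted p = 1.2e-04), and MPC1, a subunit of the mitochondrial pyruvate carrier, from 626.4 ± 35.9 to 391.0 ± 12.3 (-0.68, adjusted p = 0.0012). ODR4 (-0.74), NIPSNAP3A (-0.73), ETNK1, an ethanolamine kinase (-0.71), LAMTOR3, a subunit of the Ragulator complex (-0.68), AGO3, an Argonaute protein (-0.68), and PIGF, which acts in GPI anchor synthesis (-0.67), complete the 10. CUL7, PHGDH, RPS16, AARS1, MYH9, EIF3C, RSRP1 and PIGF lost their call under at least 1 alternative setting.

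Beyond HNRNPA1, some of the changes over 2-fold lay in copies of it or in low genes. HNRNPA1L3 fell by 1.43 and HNRNPA1P7 by 1.11 on the log2 scale. Both resemble HNRNPA1 in sequence, so their reads cannot be separated with certainty from those of HNRNPA1. CD68, a lysosomal glycoprotein gene, rose from 2.41 ± 1.69 to 16.95 ± 2.99 normalised reads (SD, n = 4; log2 fold change 2.60, limma adjusted p = 0.017), a low level at which the added 1 read understates the change. CD68 lost its call in some settings. CD68, HNRNPA1P7 and EIF3C were chosen after their values were seen.

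**Figure D1:**
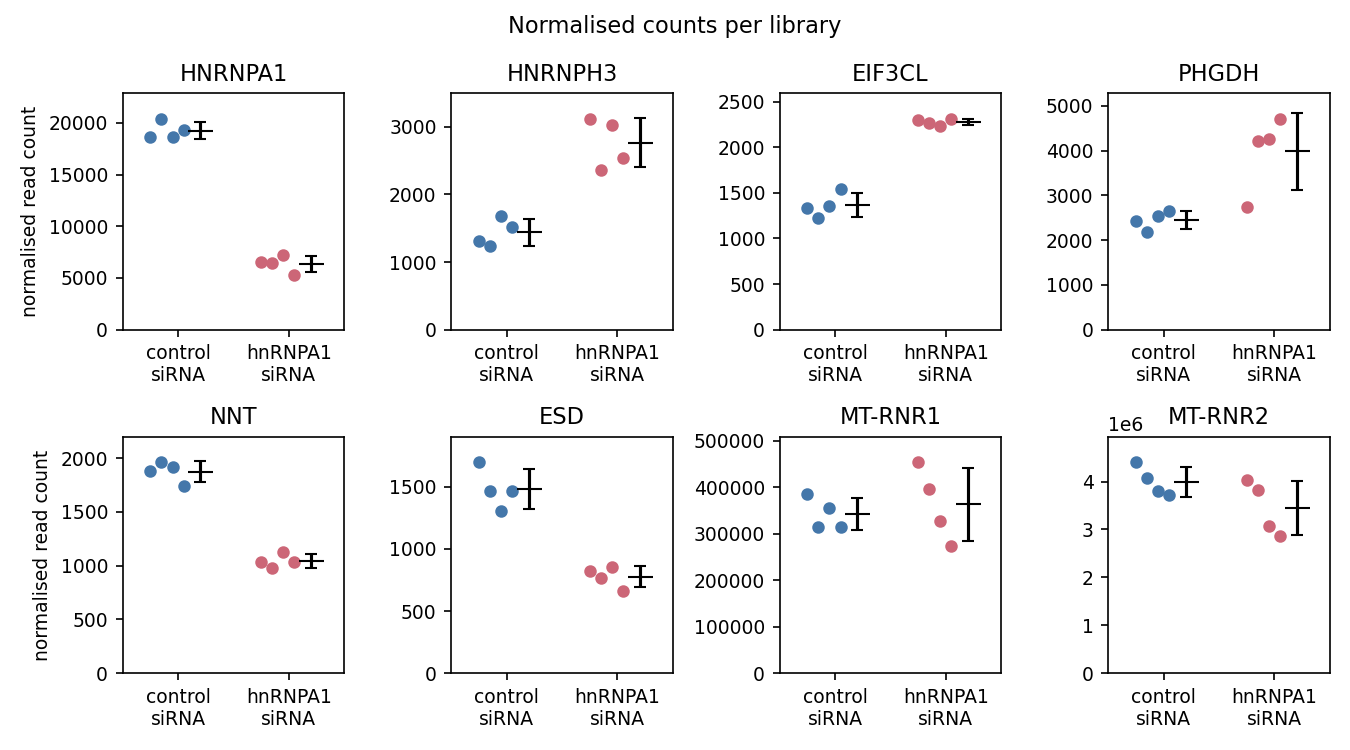
Normalised read count (y axis, linear, from 0) of 8 genes in each control siRNA and hnRNPA1 siRNA library (points, in the order of library number) with the mean and SD of 4 libraries (bar). HNRNPA1 lies between 5306 and 7185 in the knockdown libraries and at 18610 or more in the control libraries, while the groups overlap for MT-RNR1 and MT-RNR2.

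**Figure D2:**
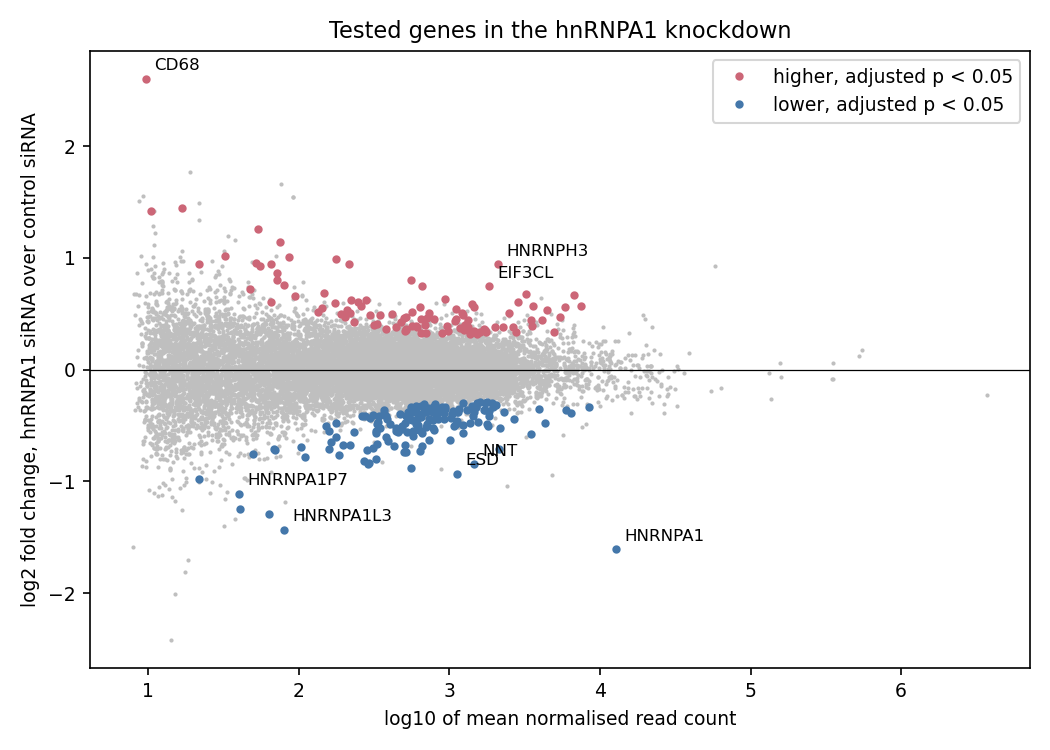
The log2 fold change of each of the 15267 tested genes (y axis, hnRNPA1 siRNA over control siRNA) against the log10 of its mean normalised read count (x axis). Coloured points are the 103 genes that were higher and the 149 that were lower at an adjusted p under 0.05, and HNRNPA1 stands out among the abundant genes at -1.61.

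The series title concerns a microprotein of mitochondria, which the labels do not name. The 12S rRNA gene MT-RNR1 holds the reading frame of MOTS-c and the 16S rRNA gene MT-RNR2 that of humanin. MT-RNR1 stood at 342700 ± 34510 normalised reads in control and 363100 ± 78180 in knockdown libraries (SD, n = 4 each; ratio of means 1.06, exact permutation p = 0.629, two-sided). MT-RNR2 stood at 3995000 ± 310700 and 3444000 ± 569700 (ratio 0.862, exact permutation p = 0.20). If the numbers pair the libraries, MT-RNR2 was lower in the knockdown library of all 4 pairs (exact sign-flip p = 0.125, the smallest that 4 pairs can give) and MT-RNR1 in 2 of 4. MT-RNR2 alone took 20.3 ± 0.521% of the normalised reads in control and 17.9 ± 2.18% in knockdown libraries (exact permutation p = 0.114). None of the 13 mitochondrially encoded mRNAs changed by limma, over all genes tested or adjusted over the list alone (0 had an unadjusted p under 0.05), and as a list they did not pass the test (camera adjusted p = 0.607). MT-CO3 stood at 58210 ± 2962 and 51850 ± 11860, and MT-CO1 at 65210 ± 6019 and 61880 ± 25120. The mRNAs together made up 1.01% and 0.899% of the reads in knockdown libraries 1 and 2 but 0.574% and 0.578% in libraries 3 and 4, against 0.761% to 0.836% in the control libraries. These values do not exclude a change of the mitochondrial transcripts that is smaller than this spread.

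Groups of genes were then tested together, each as a list. Of 76 nuclear genes of oxidative phosphorylation, 10 had a log2 fold change above 0 and the median was -0.15 (camera adjusted p = 1.3e-08, but adjusted p = 0.84 with an estimated correlation). By itself each change was small, and NDUFA5 (-0.34) and COX5B (-0.36) were the 2 members that fell (3 adjusted over the list alone). COX7A2 stood at -0.38 (adjusted p = 0.051). The cytosolic ribosomal protein genes had a median of -0.17 over 79 members, 6 of them above 0 (camera adjusted p = 1.2e-08, but adjusted p = 0.84 with an estimated correlation). RPL34 fell (-0.36) and RPS16 rose (2 and 1 adjusted over the list alone). The calls of NDUFA5, COX5B, RPL34 and RPS16 were lost in some settings. In the integrated stress response list, 23 of 24 members had a log2 fold change above 0, with a median of 0.33 (camera adjusted p = 3.5e-07, but adjusted p = 0.84 with an estimated correlation). PHGDH was the 1 member that rose over all genes tested (2 adjusted over the list alone). SHMT2 stood at 0.50 (adjusted p = 0.090) and ASNS at 0.64 (adjusted p = 0.14). The mitochondrial ribosome (median -0.05, adjusted p = 0.035), nuclear-retained RNAs (-0.15, 0.035), the cell cycle (0.08, 0.027), the hnRNP family (0.13, 0.041) and glycolysis (0.09, 0.049) also passed with the preset correlation, and each had an adjusted p = 0.84 with an estimated correlation. Of these, the mitochondrial ribosome, nuclear-retained, cell cycle and glycolysis lists had no member that changed by limma over all genes tested. They had 12, 8, 9 and 4 members at an unadjusted p under 0.05, and 0, 2, 1 and 0 passed adjusted over the list alone. With the replicate number as a block, members of each of these lists passed over all genes tested. Among them were MRPL41 (limma adjusted p = 0.0031), GOLGA8A (0.024), AURKB (0.013) and PFKL (0.023). None of the 8 lists thus passed with an estimated correlation. The fry test, which asks whether a list moves 1 way on balance, gave adjusted p of 0.289 or more for them. The mean of a list per library did not part the groups for oxidative phosphorylation (exact permutation p = 0.171), the ribosomal proteins (exact permutation p = 0.20) or the stress response (exact permutation p = 0.171). For the cell cycle the means of all 4 knockdown libraries lay above those of all 4 control libraries (exact permutation p = 0.0286), with an adjusted p = 0.6 over the lists (exact permutation tests). Within same-numbered pairs the mean was lower in the knockdown library of all 4 pairs for oxidative phosphorylation and endothelial markers. It was higher in all 4 for glycolysis, the cell cycle and the genes listed as regulated by hnRNPA1. The exact sign-flip p was 0.125 for each, so 4 pairs cannot pass the threshold. Relative to the mean of all libraries, the oxidative phosphorylation means were 0.23, 0.16, -0.07 and -0.02 in control libraries 1 to 4 and -0.04, 0.03, -0.12 and -0.17 in knockdown libraries 1 to 4. The ribosomal protein means were 0.28, 0.16, -0.10 and -0.02 in control and -0.08, 0.03, -0.10 and -0.16 in knockdown libraries. In both lists control libraries 1 and 2 thus stood above the other 6. Those of nuclear-retained RNAs were 0.03, -0.03, 0.24 and 0.11 in control and 0.16, 0.07, -0.32 and -0.25 in knockdown libraries, so that only knockdown libraries 3 and 4 lay below the control libraries. For the stress response the means were -0.34, 0.21, 0.31 and 0.59 in knockdown libraries 1 to 4. The nuclear-retained call was lost without knockdown library 3 (adjusted p = 0.278), knockdown library 4 (0.182) or control library 3 (0.244). That of the mitochondrial ribosome was lost without control library 1 (0.309) or 2 (0.102) or knockdown library 3 (0.126) or 4 (0.0545), and that of the cell cycle without control library 3 (0.140) or knockdown library 3 (0.0540). The hnRNP call was lost without control library 1 (0.141) or 2 (0.145) or knockdown library 1 (0.120), 3 (0.204) or 4 (0.0943). The glycolysis call was lost without control library 1 (0.141), 3 (0.149) or 4 (0.131) or knockdown library 2 (0.191) or 3 (0.311). Only 3 lists passed without knockdown library 3, 5 without knockdown library 4 and 5 without control library 3.

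In the hnRNP family, 1 of 30 measured members rose (HNRNPH3) and 2 fell (HNRNPA1 and HNRNPA1L3). Adjusted over the list alone the counts were 6 and 4. HNRNPA2B1, the closest relative by function, stood at 15970 ± 1757 in control and 22663 ± 4406 normalised reads in knockdown libraries (log2 fold change 0.49, adjusted p = 0.078). Of 16 measured genes that were listed as regulated by hnRNPA1, CCND1, the cyclin D1 gene, fell by 0.56 (limma adjusted p = 0.032). No other member changed in its count per gene. Such counts do not show splicing or translation, so regulation of these genes at those steps was not tested. TNFRSF10B, a p53 target that encodes a death receptor, rose by 0.33 (adjusted p = 0.037), SNHG19 among the snoRNA hosts fell by 0.57 (0.044) and SEC61G among the secretory chaperones fell by 0.32 (0.049). Adjusted over the list alone, 1 snoRNA host rose and 6 fell of 26, 2 of 29 chaperones rose and 2 fell, and 1 p53 target rose. The calls of CCND1, TNFRSF10B, SNHG19 and SEC61G were lost in some settings. The lists of the last 3 genes as wholes did not pass (camera adjusted p of 0.233, 0.190 and 0.873). No gene changed over all genes tested among the SR proteins (camera adjusted p = 0.956), the mtDNA expression factors (0.339), the interferon response (0.965), cholesterol synthesis (0.607) or the replication histones (0.321), although 2 SR protein genes, 9 mtDNA expression factors, 3 interferon response genes, 3 cholesterol synthesis genes and 2 histone genes had an unadjusted p under 0.05. Adjusted over the list alone, 1 mtDNA expression factor passed, TWNK, the mitochondrial helicase (288.0 ± 23.4 and 377.5 ± 33.0 normalised reads). These calls are without a block. With the replicate number as a block, genes of each of these lists passed over all genes tested. Among them were SRRM2 (limma adjusted p = 0.042), LONP1 (0.011), IFI35 (0.044), MSMO1 (0.013) and H2AC20 (0.047). HNRNPA2B1 (0.023) and CASP2, listed as regulated by hnRNPA1 (0.038), passed with the block as well. The median and the test differed in sign for SR proteins, snoRNA hosts, cholesterol synthesis, the interferon response and fibroblast markers, and the mean and the test for the chaperones and fibroblast markers, none of which passed. Among markers of other cell types no gene changed, and 0 had an unadjusted p under 0.05. Fibroblast markers had an adjusted p of 0.965 and endothelial markers of 0.321. The 1 lymphocyte marker tested, CD8A, stood at 11.1 ± 1.51 and 9.48 ± 1.62 normalised reads.

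The second comparison asked which RNAs were recovered with hnRNPA1 in each compartment. A gene with a peak is called bound in this text, which does not show direct binding. The authors' deposited lists hold 13007 peaks in 6967 genes for whole-cell lysate, 1519 in 1326 genes for cytosol and 1672 in 1169 genes for mitochondria. Each peak is a window of 500 bases with the peak caller's own signal value, p and q. The signal value starts at 0.70 in each list and reaches 4.68, 2.90 and 4.15. Its scale and log base are not given in the sources used here, so it ranks peaks within a list and is not compared between lists. Coordinates follow the lists, whose genome build is not given there. Protein-coding genes made up 79.7% of the whole-cell, 55.3% of the cytosolic and 77.0% of the mitochondrial genes by RefSeq symbol, which 11.6%, 22.6% and 14.9% lacked. Pseudogenes made up 2.97%, 10.9% and 3.25%, and windows in such copies cannot be told from their parent genes with certainty.

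The highest signal value in the authors' deposited whole-cell list, 4.68, lay in a window on chromosome 1 (109100193 to 109100693, plus strand) that holds SCARNA2, a small Cajal body RNA, and was shared by a window on chromosome 11 in a gene without a symbol. FCHO2 (4.51; chromosome 5, 73083041 to 73083541), TPRG1 (4.31), RPS18P12 (4.28), BCYRN1, a brain cytoplasmic RNA gene of Alu origin (4.27), and WAC (4.19) followed among named genes of that list. In the authors' deposited cytosolic list CHP1P1 and GJD2-DT (2.90 each), FRMD4A (2.75), FBXW10 (2.67), PABPC1P3 (2.61), IGFBP6 (2.57), SCARNA18B, KIAA1328P1 and PDCD5P1 (2.54 each) led among named genes. Of these only FRMD4A and IGFBP6 were among the genes tested in the knockdown. In the authors' deposited mitochondrial list ADCY8 led (4.15; chromosome 8, 130884301 to 130884801, minus strand), followed by a gene without a symbol (3.40) and, among named genes, by COL4A2-AS2 (3.22) and FNDC10 (3.20). ATP5IF1 (3.11; chromosome 1, 28237609 to 28238109), the inhibitor of the mitochondrial ATP synthase, ATP5MJ (2.79; chromosome 14, 103912288 to 103912788), a subunit of that enzyme, MT-ND2 (3.09), CDK2AP1 (3.02) and H4C9 (2.79) were also among its 10 highest. None of the genes in these lists of 10 that could be tested changed in the knockdown. The HNRNPA1 transcript itself held 3 peaks in the whole-cell and 3 in the mitochondrial list, of which the window on chromosome 12 at 54284193 to 54284693 was common to both.

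On the mitochondrial chromosome the mitochondrial list had 30 of its 1672 peaks (1.79%, exact 95% interval 1.21 to 2.55), the whole-cell list 28 of 13007 (0.215%, 0.143 to 0.311) and the cytosolic list 2 of 1519 (0.132%, 0.0159 to 0.475). The share in the mitochondrial list exceeded that in the whole-cell list (odds ratio 8.47, 95% interval 4.87 to 14.7, Fisher's exact p = 4.6e-14) and in the cytosolic list (odds ratio 13.9, 3.50 to 120, Fisher's exact p = 7.2e-07). The whole-cell and cytosolic shares did not differ by the test (Fisher's exact p = 0.764). With the peaks ranked above the median signal value alone, these odds ratios were 3.74 (1.57 to 8.32, Fisher's exact p = 0.0016) and 9.18 (1.30 to 399, Fisher's exact p = 0.012). The intervals cover counting error only, and the amount of mitochondrial RNA in each fraction is not known here. The whole-cell list held 28 mitochondrial genes with a peak and the mitochondrial list 23. The odds ratios thus compare shares of lists of unlike length, not the number of mitochondrial genes bound. Some of the windows overlap, so they are not independent.

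By kind of gene, with no test made of the difference, in the whole-cell list 21 of the 28 mitochondrial windows were assigned to tRNA genes, 6 to mRNA genes and 1 to an rRNA gene. In the mitochondrial list 12 of 30 were assigned to tRNA genes, 14 to mRNA genes and 4 to rRNA genes. The windows of the mitochondrial list were assigned to 12 tRNA, 9 mRNA and 2 rRNA genes, since some genes, such as MT-ND4 and MT-ND5, held several. A window is longer than a tRNA gene, so windows named for a tRNA also cover its neighbours. Windows named for an mRNA or rRNA gene can likewise run into a tRNA gene. The MT-ND2 window of the mitochondrial list (5470 to 5970) overlaps the MT-TW window of the whole-cell list (5512 to 6012). The counts by kind thus follow the gene assigned and may differ for nearly the same stretch. In the authors' deposited whole-cell list the highest signal values were those of MT-TT (3.70; 15888 to 16388), MT-TW (3.39; 5512 to 6012), MT-TV (3.17; 1602 to 2102), MT-TH (2.71) and MT-TF (2.55). In the authors' deposited mitochondrial list they were those of MT-ND2 (3.09; 5470 to 5970), MT-TF (2.66; 577 to 1077), the last of 4 MT-ND5 windows (2.59; 13837 to 14337), MT-TI (1.95) and MT-TV (1.89). MT-RNR2 had 3 windows in the mitochondrial list, at 1671 to 2171 (0.72), 2671 to 3171 (0.93) and 3171 to 3671 (1.17), of which that from 2671 was also in the whole-cell list (0.82). MT-RNR1 had 1 window, at 1148 to 1648 (0.73), in the mitochondrial list and none in the others. The cytosolic list held MT-TV (1.6) and MT-ND3 (0.74), both of which were in all 3 lists. Of the mitochondrial genes with a peak, 16 were common to the whole-cell and mitochondrial lists.

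**Figure D3:**
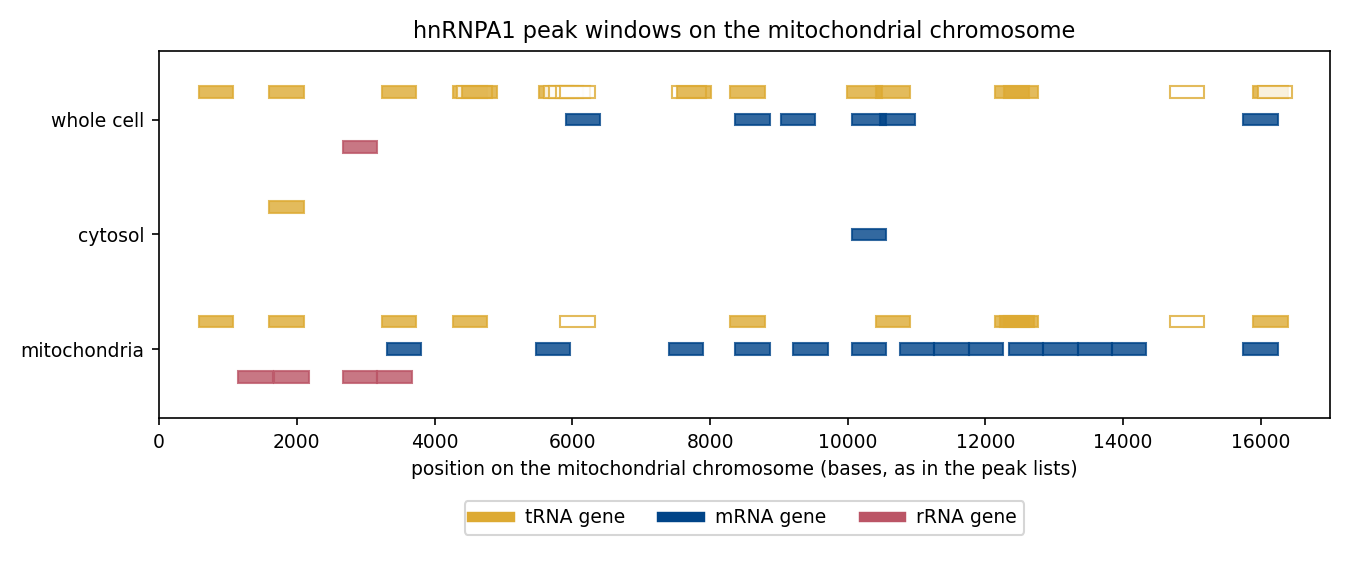
Peak windows of the 3 lists on the mitochondrial chromosome (x axis, bases as the lists give them), by the kind of gene each was assigned to; filled bars lie on the plus strand and open bars on the minus strand, and overlapping windows partly hide each other. The mitochondrial list has 30 windows, 14 of them assigned to mRNA genes, the whole-cell list 28, 21 of them assigned to tRNA genes, and the cytosolic list 2.

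Genes with a cytosolic or mitochondrial peak often also had a peak in the whole-cell list, whose lysate holds both fractions. Among the 15267 genes tested in the knockdown, 701 of the 976 with a mitochondrial peak also had a whole-cell peak (71.8%; odds ratio 4.35, 95% interval 3.76 to 5.04, Fisher's exact p = 3.9e-101), as had 463 of the 789 with a cytosolic peak (58.7%; odds ratio 2.31, 1.99 to 2.68, Fisher's exact p = 8.2e-30). Cytosol and mitochondria shared 128, which is 13.1% of the genes with a mitochondrial peak (odds ratio 3.11, 2.52 to 3.82, Fisher's exact p = 2.6e-23). Having a peak also went with expression. The share of genes with a whole-cell peak was 9.66% in the lowest of 5 equal bins of expression and 75.9% in the highest. That with a mitochondrial peak was 1.34% and 18.3%. More binding cannot be told here from easier peak calling in abundant RNAs, since no value per RIP library was analysed. Sets matched on mean expression would share 607 genes between whole cell and mitochondria (95% range 582 to 632; permutation p = 0.0001, the smallest that the draws can give), 424 between whole cell and cytosol (401 to 447; permutation p = 0.0004) and 80.8 between cytosol and mitochondria (66 to 96; permutation p = 0.0001), so each overlap exceeded its matched expectation. Among genes above the median expression the odds ratios with the whole-cell list were 2.00 for mitochondria and 1.41 for cytosol. Of the windows themselves, 351 of the 1672 mitochondrial windows (20.99%) and 176 of the 1519 cytosolic windows (11.6%) overlapped a whole-cell window on the same strand by at least 1 base. With a reciprocal overlap of at least 50%, 181 mitochondrial (10.8%) and 128 cytosolic windows (8.43%) did.

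**Figure D4:**
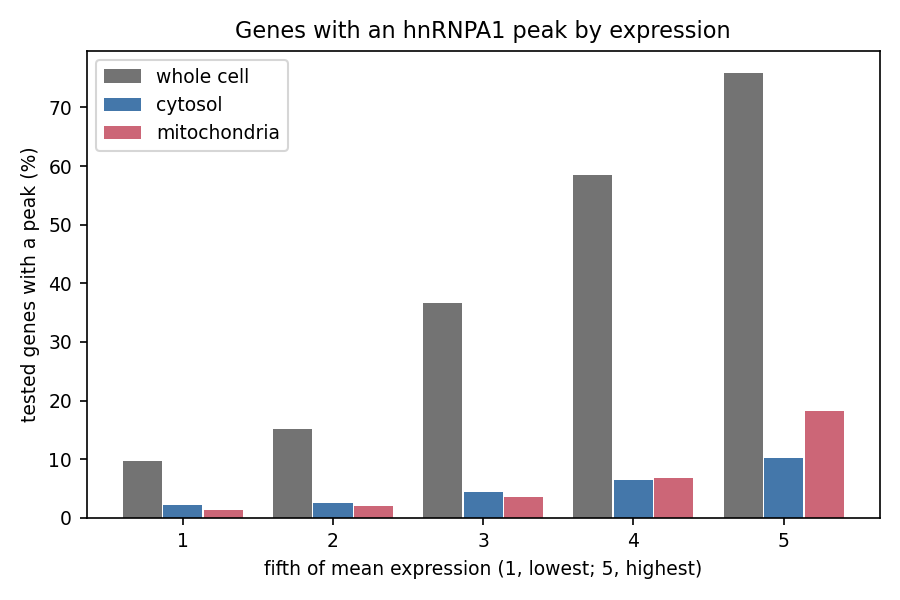
Percentage of the tested genes with an hnRNPA1 peak (y axis) in each of 5 equal bins of mean expression in the siRNA libraries (x axis), for the 3 lists (bars). The share rises from 9.66% to 75.9% for whole cell, from 2.16% to 10.2% for cytosol and from 1.34% to 18.3% for mitochondria.

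By function, 11 of 21 lists were over-represented among genes with a mitochondrial peak, 10 among genes with a whole-cell peak and none among those with a cytosolic peak at an adjusted p under 0.05 (Fisher's exact tests). For the cytosol, cholesterol synthesis (5 of 24 members, Fisher's exact p = 0.0068) and nuclear-retained RNAs (4 of 19, p = 0.015) were the lists with an unadjusted p under 0.05. Mitochondrially encoded mRNAs led in the mitochondrial list, with 9 of 13 members bound where sets matched on expression would hold 2.51 (95% range 0 to 5; Fisher's adjusted p = 2.0e-07). Expression here is that in the total RNA of the siRNA libraries. The matched sets thus do not account for how much of each RNA the mitochondrial fraction held, which is not known here. Both mitochondrial rRNAs were bound. With 2 members no count could lie above their matched range (0 to 2), so the match cannot decide for them. Of 30 measured hnRNP genes 12 were bound (matched expectation 5.90, range 2 to 10), among them HNRNPA1, HNRNPA2B1, HNRNPK and HNRNPU. Matched also on gene span the range was 2 to 11. The 12 include HNRNPA1L3, whose reads cannot be separated with certainty from those of HNRNPA1, so these may not be separate members. Secretory chaperones such as CALR, HSPA5 and P4HB had 10 of 29 members bound (matched expectation 4.35, range 1 to 8). Nuclear-retained RNAs such as MALAT1, NEAT1 and LUC7L3 had 8 of 19 (2.7, 0 to 6), and snoRNA hosts such as ZFAS1 and SNHG5 8 of 26 (2.98, 0 to 6). The ribosomal proteins, with 17 of 79 bound, lay within the matched range (13 to 27), as did the cell cycle (8 of 36, range 3 to 11). SR proteins (6 of 16, range 0 to 6), p53 targets (5 of 25, 0 to 5) and glycolysis (8 of 23, 1 to 8) lay at the upper end of their ranges. In the whole-cell list the hnRNP family (25 of 30), the cell cycle (29 of 36) and SR proteins (13 of 16) had the largest odds ratios, but all 3 lay within the range of sets matched on expression, and no list passed when the background was the genes above the median expression. Ribosomal protein genes in that list, with 50 of 79 bound, lay below the range matched on expression (56 to 70) but within that matched also on gene span (48 to 62). The snoRNA hosts in the whole-cell list, with 20 of 26 bound, lay at the upper end of the range matched on expression (11 to 20). They lay above that matched also on gene span (10 to 19). With the mitochondrial peaks above the median signal value alone, 5 lists passed.

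The last comparison joined binding and knockdown. Genes with a mitochondrial peak had a median log2 fold change of 0.04 and the other genes of 0.00 (limma's cameraPR adjusted p = 0.158, unadjusted p = 0.040), which did not pass. Genes with a whole-cell peak (adjusted p = 0.661), with a cytosolic peak (adjusted p = 0.661) and with peaks in all 3 lists (adjusted p = 0.547) did not pass either. Bound genes were called as changed more often than unbound ones: 130 of 5981 genes with a whole-cell peak (2.17%) against 1.31% of the others (odds ratio 1.67, 95% interval 1.29 to 2.16, Fisher's exact p = 6.7e-05), 28 of 976 with a mitochondrial peak (2.87%; odds ratio 1.86, 1.20 to 2.77, Fisher's exact p = 0.0040) and 22 of 789 with a cytosolic peak (2.79%; odds ratio 1.78, 1.09 to 2.78, Fisher's exact p = 0.014). Sets matched on expression would hold 131.5 (118 to 145), 21.8 (14 to 30) and 16.3 (9 to 24) changed genes, so each of the 3 counts lay within its matched range. Of 101 genes with a peak in all 3 lists 96 were tested, and 4 changed: HUWE1, a ubiquitin ligase (log2 fold change 0.56, limma adjusted p = 0.027), SMARCC2, a subunit of the SWI/SNF complex (0.38, 0.031), TRRAP, a scaffold of histone acetyltransferase complexes (0.56, 0.045), and KDM5C, a histone demethylase (0.44, 0.046). Sets matched on expression would hold 2.27 changed genes (0 to 6; permutation p = 0.2), so this count too lay within its matched range. Each of the 4 genes lost its call in some settings.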

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

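A library was looked at again where its gap to the nearest of the other 3 of its group, divided by the range of the group, exceeded the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups; of 234 groups tested 13 passed, where 11.7 would be due to chance, so no pattern is read from them. In the knockdown group library 2 was high for CUL7 (ratio 0.887; 1032 normalised reads against 742.3 to 775.0) and IQCB1 (0.844; 1167 against 1135 to 1140), and library 4 was high for MYH9 (0.891; 4633 against 4155 to 4207), ZNF528-AS1 (0.953; 143.8 against 105.5 to 107.3) and CD8A (0.894; 11.9 against 8.51 to 8.87) and low for KDR (0.916; 8.65 against 17.9 to 18.7). In the control group library 1 was low for MYH9 (0.905; 2051 against 3182 to 3300) and HK1 (0.895; 1217 against 1473 to 1503) and high for PIGF (0.964; 458.6 against 380.6 to 383.4) and SNHG32 (0.918; 1347 against 1078 to 1100), library 2 was high for TNFRSF10B (0.898; 1524 against 1358 to 1375), and library 4 was low for MT-ND4 (0.887; 2490 against 3290 to 3392) and high for H3C11 (0.880; 2386 against 2077 to 2114).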

How the results depend on the processing

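HNRNPA1 kept its fall and its call under each alternative, with a log2 fold change of -1.67 to -1.52 over the left-out libraries. Of the 43 other named genes that changed, 19 kept their call in every setting run for them and 24 lost it in some, most often with 1 library left out, with no change of direction (497 of 633 values kept the call and 136 lost it). The number of changed genes was 71 with a fold of at least 1.5 and 48 at an adjusted p under 0.01, both stricter by construction, and 61 to 254 with 1 library left out, where fewer samples enter. Samples of the 2 groups share replicate numbers, but in the paired check the deviations of same-numbered libraries correlated by 0.119, 0.292, 0.043 and 0.234, not all over 0.1, over all tested genes. Over genes above the median expression they correlated by 0.194, 0.590, 0.199 and 0.556, and over genes with a mean above 50 by 0.179, 0.493, 0.135 and 0.4505, all over 0.1. The set of all tested genes was chosen after the other values and the counts with and without the block had been seen, so the pairing stays open. Of the libraries, 5 of 8 correlated best with their own number. With a replicate block the count was 1191, 605 higher and 586 lower. Of 23 exact tests per library, 1 passed unpaired, that of the cell cycle (0.0286), and none with same-numbered pairs, whose smallest possible p is 0.125. With the block 8 lists were called, and none of the lists called without it changed direction. The number of lists called was 0 with an estimated correlation, 4 with the fold change as the ranking statistic and 3 to 9 with 1 library left out (3 without knockdown library 3, 5 without control library 3 or knockdown library 4); the cause was not tested. Peaks numbered 6504, 760 and 836 above the median signal value of the whole-cell, cytosolic and mitochondrial lists, and 614 and 923 of the cytosolic and mitochondrial peaks had a q of at most 0.005, by construction. At that q the whole-cell share of mitochondrial windows lay below the cytosolic one (odds ratio 0.924), neither difference passing. Lists over-represented among bound genes numbered 5 above the median signal value of the mitochondrial list, 1 in the cytosolic list at the stricter q and 0 in the whole-cell list against genes above the median expression; the cause was not tested. The odds ratio of mitochondrial ribosome genes in the whole-cell list turned to 0.625 above the median signal value and 0.705 against genes above the median expression, and 0 of the 2 mitochondrial rRNAs had a mitochondrial peak above the median signal value; the cause was not tested. For bound genes in the knockdown no set passed under any alternative. The cytosolic set turned to the other direction above the median signal value (adjusted p = 0.823) and at the stricter q (0.886). With 1 library left out, the adjusted p ranged from 0.31 to 0.856 for whole cell, from 0.31 to 0.856 for cytosol, from 0.0909 to 0.428 for mitochondria and from 0.191 to 0.989 for genes in all 3 lists. The direction turned for whole cell without knockdown library 2 (0.856) or 4 (0.735) and for cytosol without knockdown library 4 (0.735); the cause was not tested. The alternatives for counts were not run, since the values are not counts. Depth limits genes near the minimum of 10, and the RIP lists give no depth.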

Other observations

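The tests of scaling, per-library means, gene span, other splits and matched list expectations in this part were chosen after the results were seen. Besides the genes already described, 8 genes changed by more than 2-fold, with group means between 5.31 (MAN1A2P1 in control libraries) and 115.5 normalised reads (ZNF528-AS1 in knockdown libraries). The zinc finger gene ZNF347 rose by 1.26 on the log2 scale and ZNF528-AS1 by 1.01. PCDHGB2, a clustered protocadherin gene, rose by 1.45, MAN1A2P1 by 1.42, ZCWPW1, a histone reader gene, by 1.14 and CD2BP2-DT by 1.02. AMH, the anti-Muellerian hormone gene, fell by 1.24 and the readthrough gene NME1-NME2 by 1.29, whose reads overlap those of NME1 and NME2. The calls of PCDHGB2, MAN1A2P1, CD2BP2-DT and AMH were lost in some settings. These 8 genes were chosen after their values were seen.

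Among the 35 ways to split the 8 siRNA libraries into 4 and 4, 1 gave as many changed genes as the real one, the real split itself. If the libraries are not paired, this share of 1 in 35 argues against chance for the count of 252. It is the smallest share that the test can give, so chance is not excluded. The highest other split gave 93. That split set libraries 1 and 2 of both groups against libraries 3 and 4 of both groups, which points to a structure of the samples that the labels do not describe. If the numbers pair the libraries, only the 8 splits that part every pair compare with the real one, too few for a share under 0.125. Among these the real split gave 252 genes and the highest other 2, or 1191 and 1 with the replicate block.

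The median log2 fold change lay below 0 for the oxidative phosphorylation and ribosomal protein lists and above 0 for the stress response list, with calls that were lost with an estimated correlation (adjusted p = 0.84 for each). After quantile normalization the 3 lists kept an adjusted p of at most 9.1e-07 (camera, preset correlation). A factor per library moves all genes nearly alike, and camera compares a list with the other genes. The kept calls therefore say little about the authors' scaling. Spread between libraries stays open and may suffice: of 35 splits 14 gave at least as many list calls as the real 8 and the highest gave 12, so chance is not excluded, and the lowest exact permutation p of the 3 lists' per-library means was 0.171. The stress response mean ran from -0.58 to -0.0047 in the control libraries and from -0.34 to 0.59 in the knockdown libraries.

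Genes with a mitochondrial peak had a small median log2 fold change above 0, but as a set they did not pass (cameraPR adjusted p = 0.158). Their median of 0.0368 lay above all 10000 sets matched on expression (95% range -0.0143 to 0.0098). Among genes with a known span, their median of 0.0376 lay above the sets matched also on gene span (-0.0143 to 0.0102). If the shift is real, these values argue against mean expression and gene span as its whole cause. Transcript length was not tested. Of 35 splits 1 gave a shift between bound and other genes as large as the real 0.0352, the real split itself. The highest other reached 0.0336, so near the real value that chance is not taken as excluded. The random sets do not carry the correlation between genes, and no biological explanation was tested.

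Members of the list of nuclear-retained RNAs had peaks in the mitochondrial list more often than their expression in total RNA gives. Of 19 measured members 8 had a peak, where sets matched on expression would hold 2.7 (0 to 6). The 8 were MALAT1, NEAT1, KCNQ1OT1, CCNL2, CLK4, DDX17, LUC7L3 and PNISR. RN7SK and TUG1, which had a whole-cell peak, were not among them. Whether RNA carried over in the fractionation or binding by hnRNPA1 accounts for the 8 members cannot be told apart, since no value per RIP library was analysed.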
